A study of Homo sapiens with 9 samples.

How the data were processed

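RNA from HaCaT cells was measured by sequencing of poly(A)-selected libraries, 9 in all: 3 from cells in culture medium alone (control), 3 with 25 µg/ml fragmented polystyrene (fPS 25) and 3 with 100 µg/ml (fPS 100), each after 24 h. Per the labels, RNA was isolated with a Direct-zol kit, enriched with a NEBNext poly(A) module and made into libraries with the NEBNext Ultra II RNA kit. The sequencer output was converted with bcl2fastq, and the genome build was GRCh38.p14. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here.

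The authors' table for the series holds read counts, a whole number per gene row and library, with no normalization. Its 3 values of more than 6 digits end in 0, as if printed with 6 significant digits. The authors' 9 files per sample hold log2 values: log2 of 1 plus a value scaled for gene length and library depth, with the kind of scaling not given. The counts were used for every result, and the log2 values for 1 alternative. The count table has 58173 rows for 52402 gene symbols. Of these symbols, 2687 stand on more than 1 row. The rows of a symbol were summed, and the rows below the largest held 0.03% of the counts. In all, 20472 symbols had no count in any library. Symbols were placed on GRCh38.p14 with the RefSeq annotation, by symbol for 44651 and by synonym for 1687.

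Total counts per library ran from 16.4M to 29.3M. A count of 0 was read as allowing up to 3 counts, which is 0.102 to 0.183 CPM. Shares of counts in single libraries have 95% Wilson intervals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

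Genes were kept with filterByExpr in edgeR 4.0.16 (R 4.3.3) at a minimum count of 10 and a minimum total of 15, which left 14637. Libraries were scaled by TMM, and all 9 were fitted together by group with the robust quasi-likelihood test of edgeR, which left 6 residual degrees of freedom. The common dispersion was 0.0186, a biological coefficient of variation of 13.6%. Comparisons were fPS 100 against control, fPS 25 against control, fPS 100 against fPS 25, and any difference among the 3 groups. Tests were 2-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Fold changes are log2, n = 3 per group. Their standard error (SE) was taken as the absolute log2 fold change over the square root of the F statistic of the test. Replicate numbers are not said to mark a day or a culture, and they did not pair the libraries: none of 9 pairs with the same number correlated above 0.1. They entered as a block only in an alternative.

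Of 34 gene lists, 31 had at least 3 measured members and were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists. Each was also tested with the correlation estimated for the list, and with fry. In the lists, 708 of 722 entries matched a symbol in the table. Genes were named by a rule: for each concentration against control the 10 largest rises and the 10 largest falls, and for fPS 100 against fPS 25 the 5 largest each way, among genes called, at a mean of at least 1 CPM in the higher group and with no overlap between the libraries of the groups. Symbols that are only clone, locus or pseudogene names were passed over: 1 rise and 4 falls for fPS 100 against control, 1 and 3 for fPS 25 against control, and 2 and 1 for fPS 100 against fPS 25. In addition up to 4 members of each list with the smallest adjusted p were named. Groups, tests, lists, the naming rule and most alternatives were chosen before the data were examined. CXCL1, NSG1, CDH5 and CYP1B1, next in size after 4 ribosomal RNA genes among the rises at fPS 100, and members of a list named because 5 or fewer moved that way, were chosen after their values were seen.

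Alternatives were RLE and upper-quartile scaling, no filter on low counts or a minimum of 1 CPM in 3 libraries, a non-robust fit, limma-voom, DESeq2 1.42.0, only the compared groups in the fit, the replicate block, a minimum log2 fold change of 1, and each library left out in turn. Repeated symbols on separate rows, offsets for GC content and transcript length, the removal of ribosomal RNA genes and the authors' log2 values were added after the data were seen. The procedure was tested on simulated data with the depth and spread of these libraries. Of genes changed 2-fold, 80.6%, 77.6% and 83.6% were called in the 3 comparisons, with false calls at 5.20%, 6.25% and 8.03% of all calls. Changes were placed only in genes at 1 CPM or more in control, so recovery of lower genes was not tested. Each gene was drawn independently with the same spread in every library, so these rates do not cover a library that stands apart.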

Results

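RNA was measured in HaCaT cells, an immortalised line of human keratinocytes, the main cell type of the epidermis. Cells were kept for 24 h in medium alone or with fragmented polystyrene (fPS), a plastic broken into small pieces, at 25 or 100 µg/ml. Each of the 3 groups had 3 replicate libraries. Total counts were 22.0M, 25.4M and 23.0M in control, 16.4M, 23.4M and 22.9M in fPS 25, and 25.0M, 25.3M and 29.3M in fPS 100. The labels do not say whether the replicates are separate cultures, so p-values measure only the spread between these samples.

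On the first principal component, with 48.2% of the variance, the fPS 100 libraries lay at 39.8 to 52.8, the fPS 25 libraries at −16.9 to −11.2 and the controls at −33.8 to −26.0. The second component, with 18.7%, set replicate 3 of fPS 100 at 35.2, apart from replicates 1 and 2 of that group at −19.0 and −9.9. Of counts other than nuclear ribosomal RNA, transcripts of the mitochondrial genome for proteins took 2.09% in that replicate. They took 5.34% and 4.62% in the others of its group, and 2.32% to 3.53% in control.

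**Figure D1:**
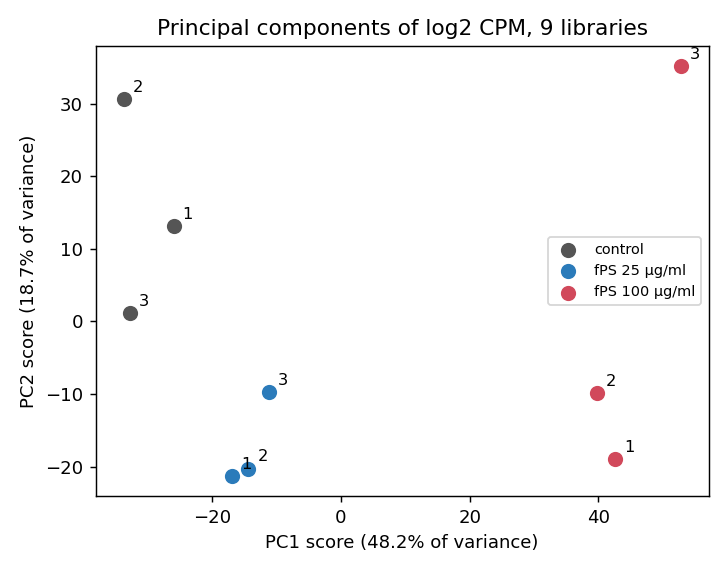
Scores of the 9 libraries on the first principal component (x axis, 48.2% of variance) and the second (y axis, 18.7%) of log2 CPM, with replicate numbers beside the points. The fPS 100 libraries lie at 39.8 to 52.8 on the x axis, and their replicate 3 lies at 35.2 on the y axis.

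Counts of nuclear ribosomal RNA stood in the fPS 100 libraries alone. RNA28S5, RNA18S5, RNA45S5 and RNA5-8S5 had 0 counts in all 6 libraries of control and fPS 25. In fPS 100 they took 6.06% (95% Wilson interval 6.05 to 6.07), 8.27% (8.26 to 8.28) and 8.48% (8.47 to 8.49) of counts in replicates 1, 2 and 3. These genes come first among the rises by the naming rule, but no fold is given, since it is not known that their reads were counted alike in all libraries. RNAs without a poly(A) tail that were counted in all 9 libraries did not rise with them. RPPH1, the RNA of ribonuclease P, fell by 2.88 log2 between fPS 25 and fPS 100 (adjusted p = 0.0380), and RN7SK, a regulator of transcript elongation, was at −2.14 (adjusted p = 0.0882).

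The comparison of fPS 100 with control asked how keratinocyte RNA differed at the higher concentration, in a series about this plastic and skin inflammation. All 28 mitosis genes and 16 of 24 genes of the ATF4 amino acid list were lower in fPS 100, while 4 of 5 genes of metal binding, 17 of 25 of antioxidant defence, 7 of 11 of xenobiotic metabolism, 7 of 14 cytokines and 8 of 19 NF-kB targets were higher. Of these lists only that of metal binding was called with an estimated correlation (adjusted p = 0.0317), the others being at 0.0681 to 0.825. FOXM1, a transcription factor of the mitotic programme, was at 210.4 ± 1.26 CPM in control and 84.8 ± 8.18 CPM in fPS 100 (mean ± SD, n = 3 per group). CYP1B1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor (AhR), was at 83.3 ± 24.3 and 768 ± 231 CPM. MT2A, a metallothionein that binds zinc, was at 143 ± 26.9 and 943 ± 386 CPM, and ASNS, asparagine synthetase, at 187 ± 7.17 and 68.9 ± 2.28 CPM.

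Of 14637 genes tested, 4393 were called, 2225 up and 2168 down, and 493 and 628 of them changed at least 2-fold. The libraries of the compared groups did not overlap for 41.4% of genes, against 10% by chance. Any difference among the 3 groups was called for 4051 genes.

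All 28 measured genes of the mitosis list fell, with a median log2 fold change of −1.09, and all 28 passed adjusted over the list alone (camera adjusted p = 3.91e-35; adjusted p = 0.0681 with an estimated correlation). FOXM1 was at −1.31 ± 0.09 (SE; adjusted p = 8.73e-06), TPX2, which builds the spindle, at −1.16 ± 0.09, KIF23, a motor of cytokinesis, at −1.10 ± 0.09, and CDC20, which activates the anaphase-promoting complex, at −1.20 ± 0.12. Of 28 DNA replication genes, 27 fell and CCNE1, cyclin E1, rose; the counts adjusted over the list alone were the same (median −1.21; camera adjusted p = 7.73e-38; adjusted p = 0.0681 with an estimated correlation). The licensing factors CDT1 and CDC6 were at −1.87 ± 0.14 and −1.32 ± 0.10, MCM10 at −1.74 ± 0.13 and RRM1, a subunit of ribonucleotide reductase, at −1.38 ± 0.10.

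Of 24 p53 target genes, 9 rose, 2 (BAX and POLH) fell and 13 did not pass, with 9 and 3 adjusted over the list alone (median 0.28; camera adjusted p = 0.00873; adjusted p = 0.0944 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, was at 1.43 ± 0.11 (adjusted p = 1.03e-05), TP53I3 at 1.30 ± 0.10 and BTG2 at 0.91 ± 0.09. Among 22 immediate early genes, 17 rose, KLF4 fell and 4 did not pass, with the same counts adjusted over the list alone (median 0.88; camera adjusted p = 4.27e-11; adjusted p = 0.0980 with an estimated correlation). The transcription factors EGR1, FOS and JUN were at 1.70 ± 0.12, 2.28 ± 0.19 and 1.35 ± 0.17, and DUSP4, a phosphatase of MAP kinases, at 1.98 ± 0.21.

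Metallothioneins and the zinc exporter SLC30A1 formed the only list called with an estimated correlation: 4 of 5 rose, also adjusted over the list alone, and none fell (median 1.91; camera adjusted p = 1.03e-10; adjusted p = 0.0317 with an estimated correlation). MT1E was at 3.15 ± 0.20 (adjusted p = 5.93e-06), MT2A at 2.72 ± 0.25, SLC30A1 at 1.91 ± 0.12 and MT1X at 1.62 ± 0.17. The NRF2 antioxidant list had 17 of 25 genes up, TXNIP, an inhibitor of thioredoxin, down and 7 not passing, with the same counts adjusted over the list alone (median 0.61; camera adjusted p = 5.58e-10; adjusted p = 0.0980 with an estimated correlation). Thioredoxin reductase TXNRD1 was at 1.74 ± 0.13 (adjusted p = 1.03e-05), the quinone reductase NQO1 at 1.20 ± 0.11 and AKR1C3, an aldo-keto reductase, at 1.54 ± 0.15. In the AhR and xenobiotic list, 7 of 11 genes rose and 4 did not pass, the same adjusted over the list alone (median 0.62; camera adjusted p = 9.54e-08; adjusted p = 0.0922 with an estimated correlation). CYP1A1 was at 4.61 ± 0.59, CYP1B1 at 3.21 ± 0.25, ALDH1A3, which makes retinoic acid, at 1.89 ± 0.11, and EPHX1, an epoxide hydrolase, at 0.87 ± 0.11.

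In the ATF4 amino acid list, 16 of 24 genes fell, 2 (the transcription factors ATF3 and ATF5) rose and 6 did not pass, with the same counts adjusted over the list alone (median −0.74; camera adjusted p = 2.75e-14; adjusted p = 0.0922 with an estimated correlation). ASNS was at −1.44 ± 0.08 (adjusted p = 2.57e-06), the serine synthesis enzymes PSAT1 and PSPH at −1.43 ± 0.09 and −1.12 ± 0.09, and CTH, which makes cysteine, at −1.76 ± 0.13. Heat shock genes had 5 of 13 down, none up and 8 not passing, with 1 up and 7 down adjusted over the list alone (median −0.31; camera adjusted p = 0.0261; adjusted p = 0.706 with an estimated correlation). These were HSP90AA1, DNAJB1, HSPH1, HSPA1B and HSPA8, with the chaperone HSP90AA1 at −0.73 ± 0.11. The unfolded protein response list had 7 of 20 down, CRELD1 up and 12 not passing, with 10 down and 1 up adjusted over the list alone (median −0.28; camera adjusted p = 0.0316; adjusted p = 0.825 with an estimated correlation), and HERPUD1, of endoplasmic reticulum protein disposal, was at −0.62 ± 0.08. The heat shock call ended without control replicate 2 (adjusted p = 0.0518), fPS 100 replicate 1 (0.0843) or fPS 100 replicate 2 (0.0555), and the unfolded protein call without the same libraries (0.0888, 0.102 and 0.158).

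Of 14 measured cytokine and chemokine genes, 7 rose and 7 did not pass, with 8 up adjusted over the list alone (median 1.61; camera adjusted p = 0.000728; adjusted p = 0.552 with an estimated correlation). Interleukins IL1B and IL1A were at 2.67 ± 0.40 (adjusted p = 0.00136) and 1.89 ± 0.31, and TNFSF15, a cytokine of the tumour necrosis factor family, at 1.43 ± 0.12. The mean log2 CPM of the cytokine list lay 0.40, 1.19 and 2.47 above control in fPS 100 replicates 1, 2 and 3, and 12 of 14 genes were highest in replicate 3. CXCL8, which draws neutrophils, had 3.23, 25.2 and 90.1 CPM in fPS 100 replicates 1, 2 and 3, against 0.835 ± 0.201 CPM in control (SD, n = 3). NF-kB target genes had 8 of 19 up and 11 not passing, with 8 up adjusted over the list alone (median 0.89; camera adjusted p = 0.0108; adjusted p = 0.825 with an estimated correlation), among them IER3 at 1.95 ± 0.27 and PTGS2, a cyclooxygenase, at 0.89 ± 0.19. Mean log2 CPM of the NF-kB list lay 0.07, 0.31 and 1.73 above control in fPS 100 replicates 1, 2 and 3, and all 19 genes were highest in replicate 3. Its call ended without that replicate (adjusted p = 0.601), and IL1B was then at 2.0. The inflammasome and pyroptosis list had 6 of 9 up, CARD8 down and 2 not passing, with 7 and 1 adjusted over the list alone (median 0.46; camera adjusted p = 0.000828; adjusted p = 0.0681 with an estimated correlation). DFNA5, the gene of gasdermin E, was at 1.15 ± 0.09 (adjusted p = 1.03e-05), NINJ1, which ruptures the plasma membrane, at 1.01 ± 0.11 and the adaptor PYCARD at 0.70 ± 0.12.

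The list of skin alarmins and antimicrobial peptides was not called (adjusted p = 0.70): RNASE7, an antimicrobial ribonuclease, rose (2.42 ± 0.36) and 6 of 7 members did not pass, the same adjusted over the list alone. Its median was −0.03, its mean 1.43 and its tested direction up. Without fPS 100 replicate 3, PI3 went from 5.83 to 0.25 and LCN2 from 2.51 to −0.79 (adjusted p = 0.00553); neither passed with all libraries, and PI3 passed without fPS 100 replicate 1 (6.41, adjusted p = 0.0478). Type I interferon genes had 8 of 34 up, 3 (HERC5, USP18 and IFIT5) down and 23 not passing, the same adjusted over the list alone (camera adjusted p = 0.254).

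Of 18 basal keratinocyte and hemidesmosome genes, 9 rose, KRT5, a basal keratin, fell and 8 did not pass, with 12 and 3 adjusted over the list alone (median 0.38; camera adjusted p = 0.0316; adjusted p = 0.825 with an estimated correlation). The integrin ITGA3 was at 1.09 ± 0.13 and KRT5 at −0.62 ± 0.10; the list call ended without control replicate 2 (adjusted p = 0.105). Epidermal differentiation genes had 6 of 20 up, 3 down and 11 not passing, with 7 and 4 adjusted over the list alone (camera adjusted p = 0.431). SPINK5, an inhibitor of epidermal proteases, was at −1.81 ± 0.23, the keratin KRT13 at −1.38 ± 0.20, and the filaggrin gene FLG fell too, while the kallikrein KLK5 was at 0.74 ± 0.09 and the transcription factor ELF3 at 0.85 ± 0.11. Epithelial junction genes had 8 of 28 up, 2 (GJA1 and PKP2) down and 18 not passing, the same adjusted over the list alone, with the tight junction gene TJP3 at 1.33 ± 0.17 (camera adjusted p = 0.119). That list passed without control replicate 3 (0.0444) or fPS 100 replicate 2 (0.0428).

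**Figure D2:**
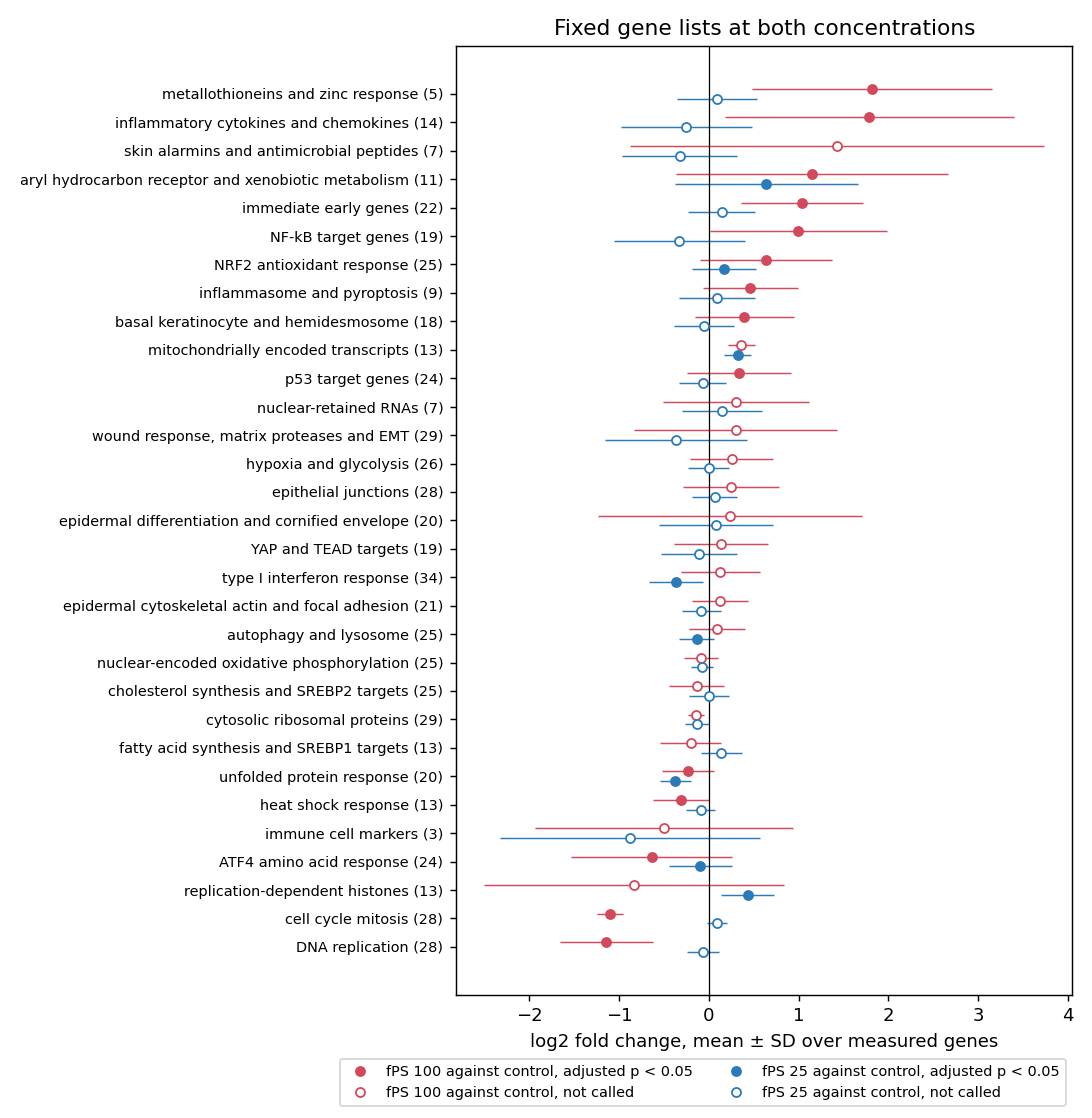
Mean log2 fold change against control over the measured genes of each of 31 lists (x axis; bars, SD over genes; number of genes in brackets) for fPS 100 and fPS 25. Filled points are lists with a camera adjusted p under 0.05: 14 for fPS 100 and 8 for fPS 25, and the mitosis and DNA replication lists lie near −1 at fPS 100 and near 0 at fPS 25.

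By the naming rule, the largest rises after ribosomal RNA were CXCL8 (chromosome 4, 73740569 to 73743716) at 5.56 ± 1.23, SPRR1A, a cornified envelope protein, at 5.04 ± 0.91, the kinase gene NEK3 at 4.69 ± 0.52, CYP1A1 (chromosome 15, 74719542 to 74725528) at 4.61 ± 0.59, IRAK2, a kinase of interleukin receptor signalling, at 3.86 ± 0.95, and FUCA1, a lysosomal fucosidase, at 3.84 ± 0.29. CXCL1 at 3.40 ± 0.84, NSG1 at 3.30 ± 0.46, CDH5, an endothelial cadherin, at 3.22 ± 0.79 and CYP1B1 (chromosome 2, 38067509 to 38076151) at 3.21 ± 0.25 were added after their values were seen. The largest falls were HMCN1, a matrix protein gene (chromosome 1, 185734391 to 186190949), at −3.95 ± 0.35, the galanin receptor gene GALR2 at −3.89 ± 0.33, ZNF114 at −3.56 ± 0.31, TEX19 at −3.42 ± 0.30, CCNT2-AS1 at −3.21 ± 0.28, ATP8B3 at −3.19 ± 0.32 and the histone gene HIST1H1D at −3.16 ± 0.63. The small RNAs RNU5F-1, SNORA17B and RNU5E-1 were at −3.44 ± 0.72, −3.38 ± 1.10 and −3.23 ± 0.89. These and HIST1H1D were highest in fPS 25 replicate 1, as was RN7SK, an RNA without a poly(A) tail. CCNT2-AS1 is antisense to another gene, and the strand setting of the counts is not known. Across all alternatives the log2 fold changes smallest in size were 0.84 for NEK3, 0.44 for NSG1, −0.42 for HMCN1 and −0.65 for ATP8B3. With the authors' log2 values, CDH5 was at 0.55 and IRAK2 at 0.37. CYP1B1 stayed at 2.965 or more, ZNF114 at −2.11 or beyond and RNU5F-1 at −2.42 or beyond.

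Some of these values changed when single libraries were left out. Such a fit has fewer replicates, so a lost call does not by itself mark that library. Without fPS 100 replicate 3, CXCL8 was at 4.09, SPRR1A at 3.90, CXCL1 at 2.42 and CDH5 at 1.74, all still called. IRAK2 was not tested without fPS 100 replicate 1 or 3, since its counts were too low, and was at 4.45 without control replicate 3. NEK3 was at 6.50 without control replicate 1, SPRR1A at 5.67 without control replicate 2 and HIST1H1D at −3.89 without fPS 100 replicate 2. The CXCL8 call ended without control replicate 1, 2 or 3 (adjusted p = 0.0562, 0.0695 and 0.0564), as did that of CXCL1 (0.0525, 0.0747 and 0.0714), and that of CDH5 without control replicate 2 (0.0700) or 3 (0.0537). Other settings ended calls too: that of CXCL8 with only these groups (0.0622) or limma-voom (0.0728). That of CXCL1 ended with no filter (0.0773), the replicate block (0.0547), only these groups (0.0595), limma-voom (0.0748) or the authors' log2 values (0.0650). That of CDH5 ended with no filter (0.111) or the authors' log2 values, and that of IRAK2 with the latter (0.117). SNORA17B was lost without control replicates 2 or 3, fPS 25 replicate 2 or any fPS 100 replicate, at 0.0582 to 0.134 and log2 fold changes of −3.98 to −2.65, and RNU5E-1 without control replicates 2 or 3 or any fPS 100 replicate, at 0.0546 to 0.114 and −3.95 to −2.50. Both were also lost with no filter (0.207 and 0.108) and the replicate block (0.0815 and 0.0746), SNORA17B with limma-voom (0.106), GC and length offsets (0.0538) or the authors' log2 values (0.161), and RNA45S5 with no filter (0.0561).

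**Figure D3:**
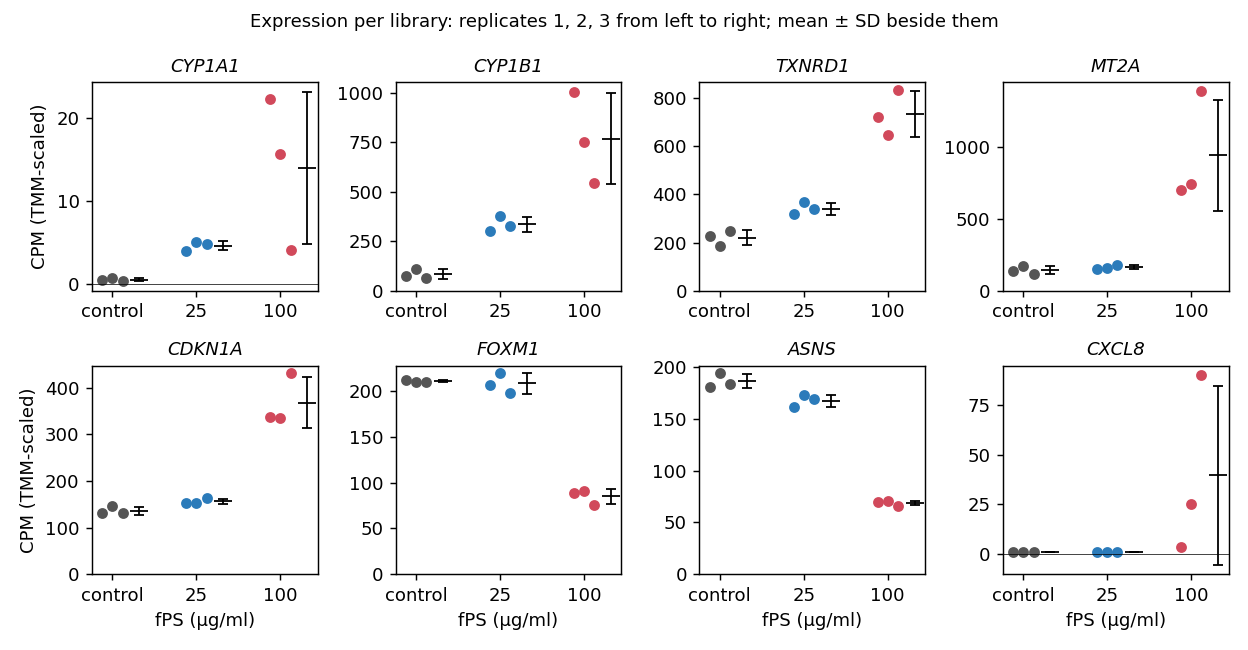
Expression in TMM-scaled CPM (y axes) of 8 genes in control, fPS 25 and fPS 100 (x axes); points are replicates 1, 2 and 3 from left to right, and bars beside them the mean ± SD of 3. CYP1A1 and CYP1B1 are above control at both concentrations, FOXM1 and ASNS are lowest in fPS 100, and CXCL8 has 3.23, 25.2 and 90.1 CPM in the fPS 100 replicates.

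The comparison of fPS 25 with control asked the same at the lower concentration. CYP1B1 was higher, at 335 ± 38.8 against 83.3 ± 24.3 CPM (SD, n = 3 per group), and CYP1A1, of the same enzyme family, was at 4.67 ± 0.565 against 0.565 ± 0.17 CPM. Of the NRF2 antioxidant list 5 of 25 genes rose, and of the type I interferon list 10 of 34 fell, with neither list called with an estimated correlation (adjusted p = 0.861 and 0.693). Among the latter the transcription factor IRF1 went from 83.4 ± 10.2 to 51.2 ± 2.29 CPM. No gene of the mitosis or DNA replication lists passed.

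Of 14637 genes, 768 were called, 439 up and 329 down, and 65 and 90 of them changed at least 2-fold. Libraries did not overlap for 33.5% of genes, against 10% by chance. The count changed when a library was left out. It was 389, 250 and 671 without control replicates 1, 2 and 3. It was 222, 135 and 225 without fPS 25 replicates 1, 2 and 3, and 1946 without fPS 100 replicate 3. Fits without a control or fPS 25 library have fewer replicates, so a lower count does not by itself mark that library. The same holds for genes and lists below that lost their call. The count was 318 with the replicate number as a block and 1511 with only these groups in the fit.

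In the AhR list 4 of 11 genes rose and 7 did not pass, with 5 up adjusted over the list alone (median 0.23; camera adjusted p = 2.58e-06; adjusted p = 0.693 with an estimated correlation). CYP1B1 was at 2.01 ± 0.24 (adjusted p = 0.00167), ALDH1A3 at 0.99 ± 0.11, CYP1A1 at 3.03 ± 0.61 (adjusted p = 0.0220) and EPHX1 at 0.52 ± 0.11. The CYP1A1 call ended without any library of control (adjusted p = 0.0709, 0.111 and 0.0789 for replicates 1, 2 and 3) or of fPS 25 (0.0559, 0.0875 and 0.0760), at log2 fold changes of 2.85 to 3.31, and with no filter (0.124), limma-voom (0.112) or the authors' log2 values (0.146). EPHX1 was lost without control replicate 2 (0.0772) or 3 (0.0538), or fPS 25 replicate 1 (0.0674), 2 (0.12) or 3 (0.0844). Of 25 NRF2 genes, 5 rose, among them NQO1, PGD, TXNRD1 and AKR1C3, and 20 did not pass, with 9 up and 1 down adjusted over the list alone (median 0.18; camera adjusted p = 0.000986; adjusted p = 0.861 with an estimated correlation). NQO1 was at 0.56 ± 0.11 and was lost without fPS 25 replicate 2 (adjusted p = 0.0682) or 3 (0.0743), and PGD without the same (0.0928 and 0.0673). TXNRD1 was lost without control replicates 1 or 2 or any fPS 25 replicate (0.0566 to 0.102).

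Type I interferon genes had 10 of 34 down, none up and 24 not passing, with 20 down and 1 up adjusted over the list alone (median −0.38; camera adjusted p = 1.56e-10; adjusted p = 0.693 with an estimated correlation). IRF1 was at −0.70 ± 0.11 (adjusted p = 0.00749) and USP18, which limits interferon signalling, at −0.55 ± 0.10. IRF1 was lost without fPS 25 replicate 2 (adjusted p = 0.0561), and USP18 without fPS 25 replicate 1 (0.0640) or 2 (0.0713). The unfolded protein response list had 2 of 20 (HERPUD1 and CRELD2) down and 18 not passing, with 12 down adjusted over the list alone (median −0.32; camera adjusted p = 6.70e-08; adjusted p = 0.861 with an estimated correlation). HERPUD1 was at −0.47 ± 0.08 and was lost without fPS 25 replicate 1 (adjusted p = 0.0556) or 2 (0.0561), and CRELD2 without control replicates 1 or 2, any fPS 25 replicate or fPS 100 replicate 2 (0.0573 to 0.172).

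Another 4 lists were called at a camera adjusted p of 0.0456, each with an adjusted p = 0.861 with an estimated correlation. The ATF4 list had SESN2 and CHAC1 down among 24 (2 up and 6 down adjusted over the list alone), and the autophagy and lysosome list GABARAPL1 down among 25 (also 1 adjusted over the list alone). None of 13 mitochondrially encoded or 13 replication-dependent histone genes passed, and none did adjusted over the list alone (medians 0.29 and 0.38, direction up). RN7SK, another RNA without a poly(A) tail, had 263.1, 159.5 and 48.2 CPM in fPS 25 and 40.7, 63.3 and 151.6 in control, so the histone call goes with a sign of RNA selection. SESN2 was lost without any fPS 25 replicate (0.0534 to 0.0653), CHAC1 also without control replicates 1 or 2 (0.0776 to 0.168 in all), and GABARAPL1 without control replicate 2 (0.0514) or fPS 25 replicate 2 (0.0797) or 3 (0.0659). The ATF4 call ended without control replicate 2 (adjusted p = 0.243), fPS 25 replicate 1 (0.156), or fPS 100 replicate 2 (0.0626) or 3 (0.0800). The autophagy call ended without control replicate 2 (0.195), fPS 25 replicate 2 (0.139) or fPS 100 replicate 2 (0.0621). The mitochondrial call ended without the same libraries (0.243, 0.135 and 0.0525), and the histone call without control replicate 1 (0.539) or 2 (0.107), fPS 25 replicate 1 (0.537) or 2 (0.160), or fPS 100 replicate 2 (0.0720) or 3 (0.0948).

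The lists of cytokines (IL6 down, none up of 14), NF-kB targets (BIRC3 down, none up of 19) and the inflammasome (DFNA5, NEK7 and NINJ1 up of 9) were not called (adjusted p = 0.571, 0.0999 and 0.108). Adjusted over the list alone, they had 1 up and 1 down, 1 down, and 3 up. DFNA5 was at 0.69 ± 0.09 (adjusted p = 0.00211). The calls of IL6 (0.0574 to 0.174) and NINJ1 (0.0667 to 0.156) ended without any library of control or fPS 25 or without fPS 100 replicate 2. BIRC3 was lost without control replicates 2 or 3 or any fPS 25 replicate (from 0.0667 up, and 0.122 without control replicate 2), and NEK7 without control replicates 1 or 2 or any fPS 25 replicate (0.0667 to 0.0999). The NF-kB list passed, downward, without fPS 100 replicate 1 (adjusted p = 0.0175) or 3 (1.22e-08). Mitosis and DNA replication genes were not called either (adjusted p = 0.158 and 0.32), with 0 of 28 passing in each, also adjusted over the list alone, at medians of 0.09 and −0.10.

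The largest rises after CYP1A1 and CYP1B1 were ZNF619 at 1.98 ± 0.32, USH1G at 1.86 ± 0.41, PGBD1 at 1.76 ± 0.18, MMP15, a membrane matrix protease, at 1.75 ± 0.18, TMOD2, a tropomodulin, at 1.64 ± 0.23, SDR42E1 at 1.59 ± 0.20, IFT46, of cilium transport, at 1.55 ± 0.18, and the long non-coding RNA MINCR at 1.53 ± 0.29. The largest falls were RTEL1-TNFRSF6B at −3.65 ± 0.36, a readthrough transcript that shares reads with both of its genes, SYT11, a synaptotagmin, at −3.25 ± 0.48, AP3B2 at −2.95 ± 0.51, and ZNF114 at −2.70 ± 0.29. They were followed by SYP, synaptophysin, at −2.45 ± 0.28, GALR2 at −2.43 ± 0.29, HMCN1 at −2.41 ± 0.31, the integrin ITGAM at −2.32 ± 0.55, CCNT2-AS1 at −2.23 ± 0.26 and TMEM198 at −2.15 ± 0.21. ITGAM was lost without any library of control or fPS 25, at adjusted p of 0.0618 to 0.113, and USH1G without control replicates 2 or 3 or any fPS 25 replicate, at 0.0633 to 0.109. MINCR was lost without control replicate 2 (0.0661) or fPS 25 replicate 1 (0.0601), 2 (0.0634) or 3 (0.0583), and AP3B2 without fPS 25 replicate 2 (0.0634). USH1G and ITGAM were also lost with the replicate block (0.0688 and 0.0804), and USH1G with the authors' log2 values (0.0595). SYT11 was at −3.94 without fPS 25 replicate 2. The size of some of these changes depended on the setting. Across all alternatives the log2 fold changes smallest in size were −0.22 for SYT11, −0.52 for AP3B2, −0.36 for HMCN1 and −0.29 for ITGAM. They were 0.38 for ZNF619 and 0.39 for TMOD2, while ZNF114 stayed at −1.75 or beyond and CYP1B1 at 1.86 or more.

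The comparison of fPS 100 with fPS 25 asked whether the concentrations differed, with no control library in the contrast. All 28 mitosis genes were lower at the higher concentration, and CDKN1A was higher, at 368 ± 55.1 against 157 ± 5.64 CPM (SD, n = 3 per group). Also higher were 4 of 5 genes of metal binding, 15 of 22 immediate early genes, 17 of 34 interferon genes, 8 of 14 cytokines and 10 of 19 NF-kB targets. With an estimated correlation the list of metal binding was called (adjusted p = 0.0158) and the other 4 of these were not (0.0712, 0.164, 0.204 and 0.434). MT2A was at 943 ± 386 against 163 ± 16 CPM.

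In this comparison 2012 genes were called, 924 up and 1088 down, and 190 and 348 of them changed at least 2-fold. Libraries did not overlap for 35.1% of genes, against 10% by chance. The count was 1095, 1018 and 1246 without fPS 25 replicates 1, 2 and 3.

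Camera calls with an estimated correlation held here for mitosis, DNA replication, metallothioneins and p53 targets. The mitosis list had 28 of 28 down, the same adjusted over the list alone (median −1.19; camera adjusted p = 1.60e-66; adjusted p = 0.0168 with an estimated correlation), with FOXM1 at −1.29 ± 0.09. DNA replication had 27 of 28 down and CCNE1 up, the same adjusted over the list alone (median −1.09; camera adjusted p = 2.29e-55; adjusted p = 0.0272 with an estimated correlation), with MCM10 at −1.58 ± 0.13. Metallothioneins had 4 of 5 up, the same adjusted over the list alone (median 1.72; camera adjusted p = 1.74e-15; adjusted p = 0.0158 with an estimated correlation), with MT1E at 2.50 ± 0.20. The p53 targets had 11 of 24 up, POLH down and 12 not passing, with 12 and 2 adjusted over the list alone (camera adjusted p = 2.15e-05; adjusted p = 0.0272 with an estimated correlation), with CDKN1A at 1.23 ± 0.11.

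Of 34 interferon genes, 17 rose and 17 did not pass, with 27 up adjusted over the list alone (median 0.43; camera adjusted p = 3.83e-11; adjusted p = 0.164 with an estimated correlation). RSAD2, an antiviral enzyme, was at 0.82 ± 0.11 and IFIT2 at 0.79 ± 0.11. Cytokines had 8 of 14 up and NF-kB targets 10 of 19, with 14 and 15 adjusted over the list alone and none down (camera adjusted p = 2.82e-07 and 5.23e-07; adjusted p = 0.204 and 0.434 with an estimated correlation). Replicate 3 of fPS 100 stood apart in both lists, with means of 2.47 and 1.73 above control, against 0.40 and 0.07 in replicate 1 and 1.19 and 0.31 in replicate 2. TNFSF15 was at 1.00 ± 0.12, IL6 at 1.56 ± 0.30 and IER3 at 1.30 ± 0.27. The inflammasome list had 5 of 9 up (DFNA5, NINJ1, PYCARD, CASP4 and CASP1), with 6 up and 1 down adjusted over the list alone (camera adjusted p = 0.00293; adjusted p = 0.0712 with an estimated correlation), and DFNA5 was at 0.46 ± 0.09. PYCARD was lost without fPS 25 replicate 1 (adjusted p = 0.0721) or 2 (0.0726), and CASP4 likewise (0.0646 and 0.0727). Immediate early genes had 15 of 22 up, with 18 adjusted over the list alone (camera adjusted p = 4.14e-14; adjusted p = 0.0712 with an estimated correlation), with EGR1 at 1.19 ± 0.12. ATF4 genes had 14 of 24 down and ATF3 up, with 16 and 2 adjusted over the list alone (camera adjusted p = 1.13e-15; adjusted p = 0.0712 with an estimated correlation), with ASNS at −1.28 ± 0.08.

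NRF2 genes had 10 of 25 up and none down, with 17 and 1 adjusted over the list alone (camera adjusted p = 1.70e-07; adjusted p = 0.164 with an estimated correlation), with TXNRD1 at 1.11 ± 0.13. In the AhR list CYP1B1, ALDH1A3, UGT1A6, TIPARP and AHRR rose, 5 of 11, with 7 adjusted over the list alone (camera adjusted p = 0.000625; adjusted p = 0.204 with an estimated correlation), and CYP1B1 was at 1.20 ± 0.23. Basal keratinocyte genes had 5 of 18 up (COL7A1, ITGA3, KRT17, LAMB3 and ITGB4), with 6 adjusted over the list alone (camera adjusted p = 0.000487; adjusted p = 0.355 with an estimated correlation), and COL7A1, the anchoring fibril collagen, was at 0.98 ± 0.12. Fatty acid synthesis had 5 of 13 down (ELOVL6, ELOVL5, ACLY, ACSS2 and PNPLA3), with 8 adjusted over the list alone (camera adjusted p = 0.00124; adjusted p = 0.355 with an estimated correlation), and ELOVL6 was at −0.54 ± 0.10. Autophagy and lysosome genes had 4 of 25 up (GABARAPL1, WIPI1, CD63 and LAMP2), with 6 adjusted over the list alone (camera adjusted p = 0.00226; adjusted p = 0.307 with an estimated correlation), and GABARAPL1 was at 0.73 ± 0.12. Heat shock genes had HSP90AA1 down of 13, also 1 adjusted over the list alone (camera adjusted p = 0.0401; adjusted p = 0.542 with an estimated correlation). The actin and focal adhesion list had ZYX, MYL12A, PXN and LIMA1 up and CAV1 down of 21, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.0425; adjusted p = 0.648 with an estimated correlation). The heat shock call ended without fPS 25 replicate 3 (0.0739) or fPS 100 replicate 1 (0.151) or 2 (0.0860), and the actin call without control replicate 2 (0.0539), fPS 25 replicate 3 (0.0882) or fPS 100 replicate 3 (0.339), with the replicate block (0.0540) or with fry (0.174).

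Several of these members lost their call when a library was left out, which also leaves fewer residual degrees of freedom. Without fPS 25 replicate 1, ACSS2 (adjusted p = 0.0799), CD63 (0.0750), MYL12A (0.0939) and TIPARP (0.0655) did, and without fPS 25 replicate 2, ACLY (0.0534), ACSS2 (0.0814), CD63 (0.0877), WIPI1 (0.0570) and MYL12A (0.0889). TIPARP was lost without fPS 25 replicate 3 (0.0729) or fPS 100 replicate 1 (0.0510), and ACSS2 (0.0667) and MYL12A (0.0559) without fPS 100 replicate 2. Without any of the fPS 25 replicates LAMB3 (0.0570 to 0.0712) and ZYX (0.0526 to 0.0577) were lost. HSP90AA1 was lost without any fPS 25 replicate or fPS 100 replicate 1 (0.0502 to 0.0857), and LAMP2 without control replicate 1, any fPS 25 replicate, or fPS 100 replicates 1 or 2 (0.0749 to 0.146).

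By the naming rule, CXCL8 was the largest rise after ribosomal RNA, at 5.69 ± 1.27, and at 4.22 without fPS 100 replicate 3. Its call ended without control replicate 1, 2 or 3 (adjusted p = 0.0539, 0.0550 and 0.0556) or fPS 25 replicate 1, 2 or 3 (0.110, 0.123 and 0.112). Control libraries enter this comparison only through the shared filter, scaling and spread, so a call lost without one does not mark that library. The largest falls were all RNAs of histones or small non-coding RNAs, and all were highest in fPS 25 replicate 1, where RN7SK, another RNA without a poly(A) tail, was highest too. RNU5E-1 had 3.33, 7.01 and 15.6 CPM in control, 22.5, 10.4 and 4.03 in fPS 25 and 0.767, 0.333 and 1.61 in fPS 100. RN7SK had 40.7, 63.3 and 151.6 CPM in control, 263.1, 159.5 and 48.2 in fPS 25 and 33.9, 40.2 and 30.8 in fPS 100. These falls thus go with a sign of RNA selection. For the histone genes this was not told apart from the fall of 27 of 28 DNA replication genes in the same comparison. HIST1H2AD, with 0 counts in all fPS 100 libraries, was at least 3.63-fold lower there, for the lowest fPS 25 library over the largest floor of 3 counts. The Y RNA RNY4 was at −4.32 ± 0.99, the spliceosomal RNU5E-1 at −3.73 ± 0.90, HIST1H3I at −3.59 ± 0.70 and SCARNA10 at −3.44 ± 0.72. Without fPS 25 replicate 1 these were at −3.51, −2.98, −3.00 and −2.72, with RNY4 (adjusted p = 0.0582) and RNU5E-1 (0.0607) no longer called. RNY4 was also lost without fPS 100 replicate 1 (0.0577), and was at −6.02 without fPS 100 replicate 3. RNU5E-1 was also lost without control replicate 2 (0.0606), fPS 25 replicate 2 (0.0791) or fPS 100 replicate 1 (0.115), 2 (0.0912) or 3 (0.0622, at −4.44). With no filter CXCL8 (0.0745), RNU5E-1 (0.11) and RNA45S5 (0.0947) were not called, with the replicate block RNU5E-1 (0.0902), and with the authors' log2 values CXCL8 (0.0713) and RNY4 (0.111). CXCL8 was also lost with only these groups (0.0847) and with limma-voom (0.126).

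Both concentrations were compared with the same controls, so their fold changes correlate even with no effect. Of 768 genes called at fPS 25, 84.8% were also called at fPS 100 in the same direction. In all, 393 genes rose at both and 258 fell at both. The number to be had from shared controls alone was not computed. Pearson's r across 14637 genes was 0.477 (Spearman's rho 0.587), and genes are not independent replicates. Simulated groups with no effect against shared controls gave r of 0.494 ± 0.0329 (SD, 30 simulations). The 4 ribosomal RNA genes had no counts in the simulations, so the observed r to set beside this is that without them, 0.541. Fold changes had the same sign for 72.6% of genes, against 66.7% simulated. The covariance was 0.137 with or without the 4 ribosomal RNA genes, above the 0.0362 ± 0.00328 of the simulations. Each gene was drawn independently in the simulations, so their SDs leave out spread that genes share. The simulations therefore cannot tell a shared response from control differences common to many genes. Genes called in opposite directions numbered 5: COL7A1 was at 0.52 at fPS 100 and −0.45 at fPS 25, while CDCA7, CKAP2L, ARHGEF39 and SAPCD2 fell at fPS 100 and rose at fPS 25. COL7A1 was no longer called at fPS 25 without any library of control or fPS 25, or without fPS 100 replicate 1 (adjusted p = 0.0536 to 0.208).

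**Figure D4:**
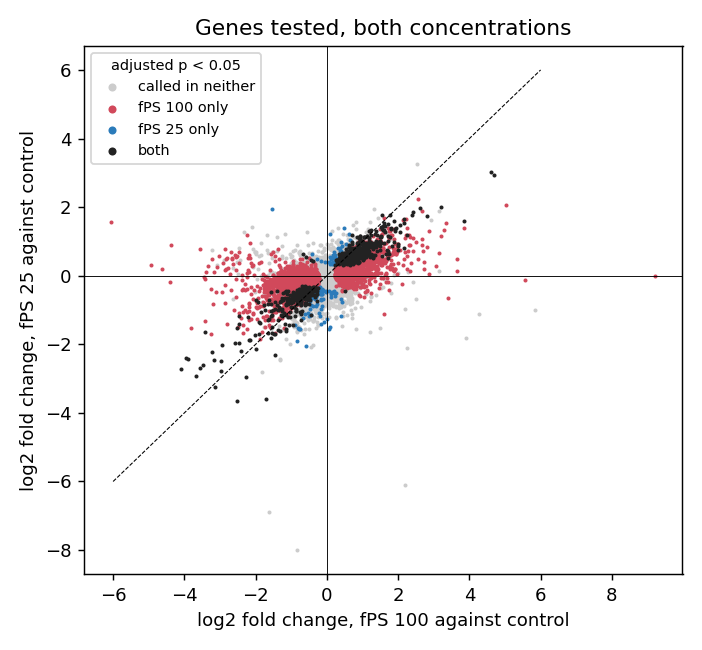
Log2 fold changes of each tested gene at fPS 100 (x axis) and fPS 25 (y axis), both against control; colours mark where a gene was called and the dashed line marks equal change. The 4 ribosomal RNA genes, with 0 counts in 6 libraries, are left out, and 651 of the 656 genes called at both concentrations changed in the same direction.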

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

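Of the tests weighed here, those of the calls without ribosomal RNA, of GC content in replicate 3 and of a larger response in replicate 3 were written before the result was seen, and all others were chosen only after the result was seen.

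Nuclear ribosomal RNA took 6.06%, 8.27% and 8.48% of counts in the fPS 100 libraries and none in control or fPS 25. Weaker poly(A) selection in the fPS 100 libraries is argued against, since 5 other RNAs without a poly(A) tail were at a median log2 difference of −2.14 between fPS 100 and fPS 25 and −1.27 between fPS 100 and control, though none of the 5 was called against control and RN7SL2 was at −0.14 there, lower in control replicate 1 (54.3 CPM) and fPS 25 replicate 3 (66.9) than in any fPS 100 library. That all 6 other libraries had exactly 0 counts is consistent with ribosomal RNA reads having been removed or not counted for control and fPS 25. Every cell holds nuclear ribosomal RNA, and the 5 RNAs without a poly(A) tail each kept at least 458 counts in the same 6 libraries. The exact zeros thus did not arise in the cells. Mitochondrial ribosomal RNA took 1.37% to 1.83% of counts in these libraries. Which step of the library or the counting gave the zeros stays open.

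The large number of genes called in fPS 100 against control might have come from technical differences that go with the group. GC content and transcript length are argued against, as 96.0% of calls stayed in the same direction with offsets for both, and so is the share taken by ribosomal RNA, as 99% stayed without it. The same offsets ended 3 of the 14 list calls: heat shock (adjusted p from 0.0261 to 0.0904), unfolded protein response (0.0316 to 0.0603) and basal keratinocyte genes (0.0316 to 0.0909), where this bias stays open. A batch or processing run of its own for the fPS 100 libraries cannot be told from the concentration: 5 symbols, 4 of them ribosomal RNA genes, had 0 counts in the 6 other libraries and at least 5 in each fPS 100 library. The labels give no batch, so this stays open for the results of fPS 100.

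Replicate 3 of fPS 100 stood apart, with most of the NF-kB, cytokine and alarmin RNA of its group. GC content and length explained 12.8% of the variance of its difference from the others. Immune, endothelial, fibroblast or melanocyte cells are unlikely, as 2 of 37 of their markers (CDH5 and ITGAM) reached 1 CPM and 2 times the mean of the other replicates. These markers do not cover other epithelial cells, which stay open. A larger response is argued against as the whole cause, as its difference from each other replicate correlated with the response of the remaining one at −0.147 and −0.12. Mean log2 changes were largest in replicate 3 for mitosis (−1.33, against −1.12 and −0.89), DNA replication (−1.41, against −1.10 and −0.95), immediate early (1.29, against 0.80 and 0.85) and NRF2 genes (0.76, against 0.59 and 0.48). For these lists a larger response stays open, as does the source of the rest. Changes were smallest in replicate 3 for the AhR list (0.83, against 1.34 and 1.14), metallothioneins (1.67, against 1.77 and 1.94) and the ATF4 list (−0.58, against −0.66 and −0.71).

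Splits of the libraries into mixed groups are too few in each pair of groups for a share under 0.05, with 10 in all. The real grouping was the 1 with most calls in each: 4393 genes against 0 at most in the others for fPS 100 and control, 768 against 5 for fPS 25 and control, and 2012 against 0 between the concentrations. Among all 3 groups, 1 of 100 splits had as many calls, the real one with 4051, and the highest other had 1566. Camera called at least as many lists in 7 of 10 splits for fPS 100 against control (14 in the real one, 16 at most in the others), 4 of 10 for fPS 25 against control (8 and 10), and 9 of 10 between the concentrations (17 and 21). The number of lists called therefore carries no evidence for the grouping. For fPS 100 against control, the camera adjusted p of NF-kB targets was as small or smaller in 9 of 9 other splits. The same held in 5 for basal keratinocyte genes, 4 for cytokines, 3 each for heat shock and unfolded protein genes and 1 for p53 targets. No other split was as small for the remaining lists called, though mitosis genes were still called in 8 of 9. For fPS 25 against control, 5 other splits were as small for histones and 4 each for ATF4 and mitochondrial genes. NRF2 and autophagy genes had 2 each, interferon genes 1, and AhR and unfolded protein genes none. Between the concentrations, NF-kB and actin genes had 6 each, cytokines and heat shock 3 each, and basal keratinocyte and fatty acid genes 2 each. Interferon, NRF2, AhR and autophagy genes had 1 each, and the other lists called none.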

How the results depend on the processing

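All alternatives were chosen before the data were examined except repeated symbols on separate rows, the removal of ribosomal RNA genes, the GC and length offsets and the authors' log2 values, and tests of the causes of these shifts were not made. The number of genes called in fPS 25 against control, 768, was the least stable: 1237 with no low-count filter, 1241 with DESeq2, 1333 with GC and length offsets, 1511 with only these groups, 318 with the replicate block, 155 at a log2 fold change of at least 1, and 135 to 1946 with a library left out. A log2 fold change of at least 1 gave 1121 genes in fPS 100 against control and 538 between the concentrations, where leaving out a library gave 1018 to 2706. With an estimated correlation 1, 0 and 4 lists were called in fPS 100 against control, fPS 25 against control and fPS 100 against fPS 25. For fPS 25 against control 3 lists were called with fry, among them the inflammasome list (0.0385), 4 without ribosomal RNA genes, 4 with GC and length offsets, and 4 to 10 with a library left out; the 4 lists lost in both added settings are those at 0.0456. With fry 11 lists were called in fPS 100 against control, without NF-kB (0.202), basal keratinocyte (0.0798) and unfolded protein genes (0.113), and 15 between the concentrations, without NF-kB (0.0886), heat shock (0.0695) and actin genes (0.174) and with cholesterol synthesis (0.0395). Between the concentrations the replicate block ended the actin call (0.0540), and the offsets ended the heat shock and actin calls (0.0723 each). The correlation of fold changes at both concentrations was 0.539 without ribosomal RNA genes and 0.422 to 0.541 with a library left out. Signs reversed for LCN2 in fPS 100 against control, from −0.79 without fPS 100 replicate 3 to 3.05 without fPS 100 replicate 2, and for the mitochondrially encoded list between the concentrations, scored −1 without control replicate 1 and 1 without fPS 100 replicate 3 (adjusted p = 0.0186); the cause was not tested. No gene called with all 9 libraries changed sign when a library was left out. Beyond left-out libraries, members of lists lost calls in other settings too: at fPS 25 IL6 in 6, COL7A1 in 4, NINJ1, BIRC3 and CRELD2 in 2 each and NQO1, PGD, NEK7 and CHAC1 in 1 each, at fPS 100 HSPA1B in 2, and between the concentrations LAMP2 in 5, MYL12A in 2 and KRT17 and ACSS2 in 1 each.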

Other observations

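Lists not described so far were not called in fPS 100 against control, yet held single genes that changed. In the wound response and matrix protease list 8 of 29 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.714). PLAU, the urokinase gene, was at 1.65 ± 0.28 (SE) and VIM, vimentin, at −2.18 ± 0.34. In the hypoxia and glycolysis list 7 of 26 rose and 2 (ALDOC and GPI) fell, with 8 and 2 adjusted over the list alone (camera adjusted p = 0.123), and it passed without fPS 100 replicate 1 (0.0191) or 2 (0.0257). In the replication-dependent histone list 3 of 13 rose and 6 fell, with 4 and 6 adjusted over the list alone (camera adjusted p = 0.932), at a median of −0.89 and a mean of −0.84 with the tested direction up. None of 29 cytosolic ribosomal protein genes and none of 13 mitochondrially encoded transcripts passed (camera adjusted p = 0.203 and 0.22), also adjusted over the list alone. The ribosomal protein list passed, downward, without control replicate 3 (0.0128), and the mitochondrial list, upward, without fPS 100 replicate 3 (0.000178). The lists of cholesterol synthesis, fatty acid synthesis, autophagy, YAP targets, actin, oxidative phosphorylation, nuclear-retained RNAs and immune cell markers were not called (camera adjusted p = 0.239, 0.22, 0.381, 0.411, 0.287, 0.431, 0.55 and 0.661).

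In fPS 25 against control the remaining lists were not called, with camera adjusted p from 0.056 for cytosolic ribosomal proteins to 0.767 for differentiation. The ribosomal protein list, with 0 of 29 passing, passed as a list, downward, without control replicate 3 (0.000182), fPS 25 replicate 3 (0.00107) or fPS 100 replicate 1 (0.0483), oxidative phosphorylation without control replicate 3 (0.0155), fatty acid synthesis, upward, without fPS 25 replicate 3 (0.0387), and the wound list, downward, without fPS 100 replicate 3 (0.00077). Between the concentrations cholesterol synthesis, at 0.0542, was lower at fPS 100 without control replicate 2 (0.035) or 3 (0.0449) or fPS 100 replicate 3 (0.0119). Hypoxia, at 0.0638, passed without fPS 25 replicate 3 (0.0484) or fPS 100 replicate 1 (0.00745) or 2 (0.00801), and the wound and YAP lists, at 0.133 and 0.0991, without fPS 100 replicate 1 (0.00624 and 0.0378) or 2 (0.00698 and 0.0422). Junctions, at 0.0885, passed without fPS 25 replicate 1 (0.0403) or fPS 100 replicate 2 (0.0296), histones, at 0.134, without fPS 25 replicate 3 (8.51e-05), and alarmins, at 0.525, without fPS 100 replicate 1 (0.0348).

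Of 3 measured immune cell markers at fPS 100, CD68, which is also a lysosomal protein gene, rose by 1.16 ± 0.11 (SE; adjusted p = 4.30e-05), ITGAM was at −1.44 ± 0.49 (adjusted p = 0.0452) and CD14 at −1.22 ± 0.53 (adjusted p = 0.103, not called). The ITGAM call ended without any control library, fPS 25 replicates 1 or 2, or fPS 100 replicates 1 or 2 (adjusted p = 0.0532 to 0.136), and with the replicate block (0.0724), and ITGAM was at −2.25 without fPS 100 replicate 3 (0.00318). Of 7 nuclear-retained RNAs, NEAT1 and MALAT1 rose by 1.58 ± 0.22 and 1.02 ± 0.23, SNHG1 and GAS5 were at −0.55 ± 0.10 and −0.59 ± 0.13, and 3 did not pass. These genes were chosen after their values were seen.

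Of the AhR list 7 of 11 genes and of the cytokine list 7 of 14 rose at fPS 100, and the test of their link was chosen only after the result was seen. The AhR list lay 0.83 above control in fPS 100 replicate 3, which had most cytokine RNA, and 1.34 and 1.14 above it in replicates 1 and 2, with an SD of 1.51 over the log2 fold changes of its 11 genes. With 3 libraries this cannot tell a shared cause from separate ones. Cultures with washed particles, and with medium that had held particles, would test this.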
